A study of Mus musculus with 2 samples.

How the data were processed

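Total RNA of 2 cultures of activated mouse CD8+ T cells, 1 with DMSO and 1 with bezafibrate at 30 µM, was amplified with a whole-transcript kit, labelled with biotin and hybridised to Affymetrix gene arrays, per the labels' protocols. The labels name 1 array for each group and no further cultures or animals, so the number of arrays limits the precision, among other limits given below. No value has a replicate error.

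The deposited values are log2 signals of probe sets, made with RMA in Affymetrix Expression Console, per the submitters' processing notes; their versions are not given in the sources used here. RMA corrects background, equalises the distribution of probe signals between arrays that are processed together and summarises the probes of each set, so a change shared by most genes would be removed before deposit and every ratio is relative to the other genes. That the scale is log2 was read from the values, which ran from 0.75 to 12.68 in control and from 0.79 to 12.64 with bezafibrate, with column medians of 4.58 and 4.55. The sorted values of the columns differed by at most 0.11. RMA shrinks differences at low signal, so ratios of dim genes are understated.

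The table held 41801 probe sets, of which 8008 were blank on both arrays and none of those carried a gene symbol. Of the 33793 with values, 23521 named exactly 1 gene in the platform annotation, 1814 named several and 8458 none. On 1904 probe sets (5.63%) both arrays held exactly equal values. Only probe sets with 1 symbol were used, and of several for a gene the one with the highest mean of both arrays stood for it, as for 1082 of the 22180 genes. Where 2 probe sets of a gene lay above the floor, in 441 genes, their ratios correlated with a Spearman's rho of 0.21 across genes and had the same sign in 55.8%, so a single small ratio is poorly determined. Gene lengths and RNA classes came from the RefSeq annotation of assembly GRCm38.p6, matched by symbol or gene number, which gave a length for 99.2% of genes. No build is named in the sources used here, so no coordinates are given.

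The log2 ratio was bezafibrate minus control. A gene was above the floor when its brighter array exceeded that array's median over all named genes (4.88 in control and 4.85 with bezafibrate). Genes were counted as different at 2-fold, with 1.5-fold and 3-fold as alternatives. Olfactory and vomeronasal receptor genes served as silent reference genes for the background. Each of 31 gene lists and 10 cell marker lists, holding 788 gene names of which 700 had a value, was described by its median log2 ratio and by the percentile of that median among 10000 random lists of the same size drawn within 20 classes of mean level. A list stood apart when it lay outside the central 95%, that is below percentile 2.5 or above 97.5. These percentiles describe the arrays and are not p-values.

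The lists, limits and alternatives were fixed before the data were examined, and so was the rule for named genes. The rule took the 12 largest increases and 12 largest decreases above the floor, leaving out predicted, clone-named, small RNA, antigen receptor segment and sensory receptor genes (1015 genes above the floor, 211 of them small RNA genes). It added up to 2 members of each list with the highest and 2 with the lowest ratio above the floor, and a fixed set of genes of PPAR signalling, fatty acid oxidation and T cell function that are always named. It covered 171 genes, of which the text names those that describe each group. Alternatives were another floor or none, quantile normalization, a loess curve of the ratio on level, centring on housekeeping genes, the mean or the smallest ratio over a gene's probe sets, probe sets of several genes included, and for lists no matching on level, only members above the floor, the mean in place of the median, and leaving out the member farthest from the median. After seeing the data, 2 alternatives were added. Random lists were matched on both level and gene length in 10 by 10 classes, and the median ratio of each such class was subtracted from its genes.

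Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6, and plots used matplotlib 3.10.9. The list percentiles and the 2-fold rule were tested on simulated data for this comparison, with 10 simulations of the 22180 genes and a noise SD of 0.2 on the log2 scale. Of unchanged lists, 4.1% fell outside the central 95%, and 90.5% of lists shifted by 0.2 were found. With a trend with gene length added, 7.1% of unchanged lists fell outside when matched on level and 3.9% when matched on level and length. Of genes changed 1.5-fold, 2-fold and 4-fold, 2.5%, 54.9% and 100% passed the 2-fold limit. The simulated noise was below that of the silent genes, whose log2 ratios had a robust SD of 0.30. It was independent between genes, and the simulated length trend had the same slope at every level. In the data Spearman's rho of ratio and length was 0.13 at mean log2 levels under 6 and 0.49 at 9 or more. These rates may therefore not hold for lists of genes that vary together.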

Results

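Gene expression was measured in mouse CD8+ T cells on 2 arrays, 1 for cells grown with bezafibrate and 1 for cells grown with its solvent, dimethyl sulfoxide (DMSO), as the control. Naive cells had been activated through CD3, part of the T cell receptor complex, and CD28, its main costimulatory receptor, by beads carrying antibodies to both, with interleukin-2 at 100 U/mL. Bezafibrate, a lipid-lowering fibrate that activates the peroxisome proliferator-activated receptors (PPARs), was present at 30 µM throughout, and expansion ran to day 13. PPARs are nuclear receptors that control genes of fatty acid uptake and oxidation, and the comparison asks which genes differ in T cells cultured with such an agonist. With 1 array per group there is no replicate spread to set a difference against. No p-value is given, and every ratio compares 2 arrays, not 2 conditions.

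Of 22180 genes with a value, 11446 lay above the floor, the median level of all named genes, on their brighter array. Above the floor the median log2 ratio of bezafibrate over control was 0, and 95% of genes had ratios between −0.42 and 0.41. Across genes, which are not independent replicates, Pearson's r between the arrays was 0.993 and Spearman's rho 0.991. Background was read from 1394 olfactory and vomeronasal receptor genes, which T cells are not known to use. Of these, 119 (8.54%) differed at least 1.5-fold between the arrays and 11 (0.789%) at least 2-fold. Their 95th percentile was a log2 level of 4.71 on the control array and 4.68 on the bezafibrate array, and a level under it is called within background.

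In the bezafibrate array, 10 genes above the floor were at least 2-fold higher and 0 were at least 2-fold lower. The 3 protein-coding genes among them were Gzmd, Tlcd1 and Klrc2. Gzmd (probe set 17306991), a granzyme of cytotoxic granules, had a log2 level of 2.76 in control and 4.90 with bezafibrate. The control level was within background, and against the background limit the bezafibrate level was 1.14-fold higher. Gzme, its near-identical neighbour, was read only by a probe set that also names Gzmd, at 2.14 and 2.69. Tlcd1 (probe set 17266368), which limits polyunsaturated fatty acids in membrane phospholipids, had levels of 7.15 and 8.29, a 2.20-fold difference. Its second probe set had a log2 ratio of −0.14, so the direction rests on the brighter probe set. Klrc2 (probe set 17471586), the activating NKG2C receptor, had levels of 4.01 and 5.05, with the control within background and a 1.26-fold difference against its limit. The other 7 genes encode small RNAs, with 6 small nucleolar RNAs and the microRNA gene Mir669a-3, whose log2 ratio was 1.10.

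With small RNA, predicted and clone-named genes left out, the next largest increases were in Hadhb, Zxdb, Zfp119a, Dpep2, Clpsl2, Plin2, Zgrf1, Tmem81 and Orm2, with log2 ratios from 0.92 for Hadhb to 0.75 for Orm2. The control level lay within background for Zfp119a, Clpsl2, Tmem81 and Orm2, and a second probe set of Dpep2 had a ratio of −0.40 against 0.86 for the first. With the same genes left out, the largest decreases were in H2bc9, a core histone gene, at −0.95 (5.72 in control and 4.76 with bezafibrate), Eif4a3l1 at −0.93, Fcer1g at −0.93 and the linker histone gene H1f1 at −0.91. Fcer1g, which encodes the signalling chain shared by Fc receptors, had levels of 6.57 and 5.64. With probe sets that name several genes included, the ratio of Eif4a3l1 was 0.04. Prss1, Luzp4, Zfp358, Pnmal2, Rbfox3, Foxi3, Amacr and Phospho2 followed, with ratios from −0.90 for Prss1 to −0.79 for Phospho2. The bezafibrate level lay within background for Prss1, Luzp4, Pnmal2, Foxi3 and Amacr. At a 1.5-fold limit, 76 genes were higher and 60 lower. Protein-coding genes alone went the other way, with 33 higher and 53 lower, and 25 of the 76 were small nucleolar RNA and 10 microRNA genes. With no floor the 2-fold counts were 20 higher and 20 lower, and with the floor at the 75th percentile they were 3 and 0.

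**Figure D1:**
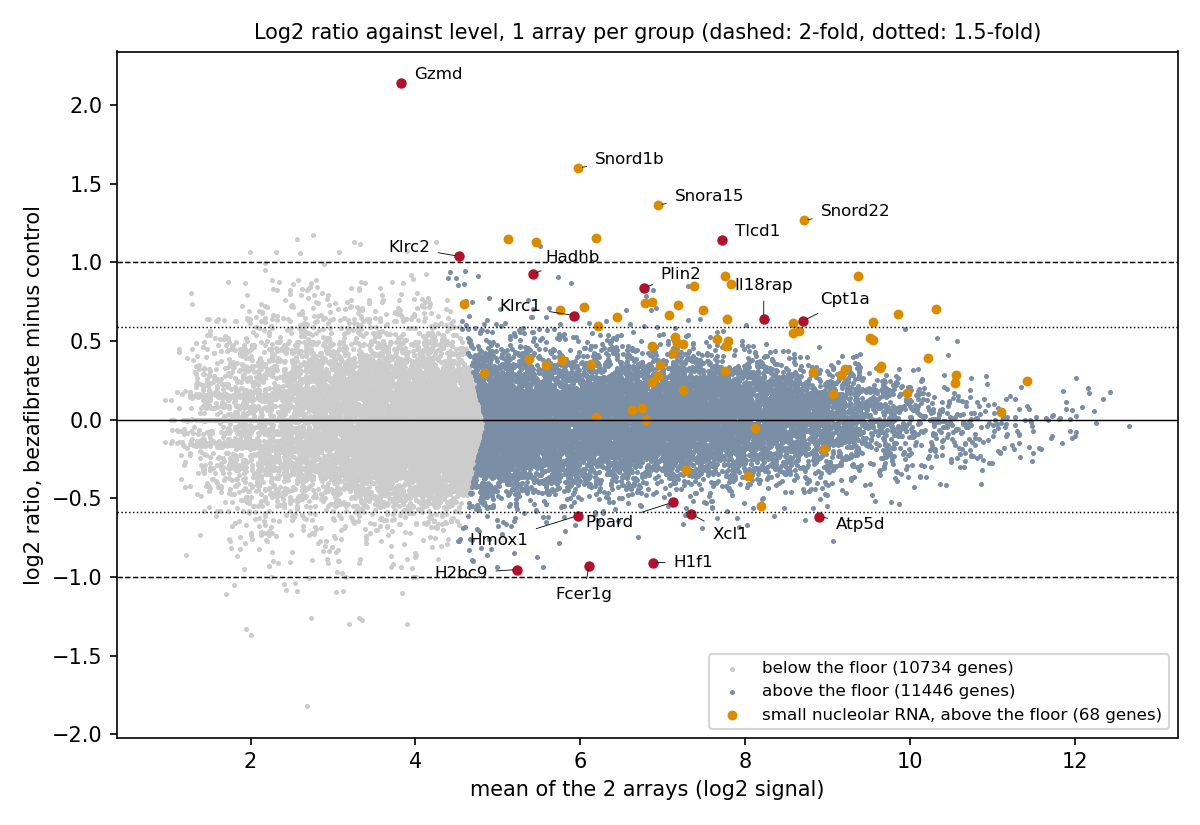
Log2 ratio (bezafibrate minus control) of each gene against the mean log2 level of the 2 arrays, with genes below the floor in pale grey, genes above it in blue, small nucleolar RNA genes above it in orange and other labelled genes in red. The median of the orange points, 0.48, lies above the band from −0.42 to 0.41 that holds 95% of genes above the floor, while their 25th percentile, 0.28, lies inside it; the control level of Gzmd, the topmost point, is within background.

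Genes of fatty acid oxidation and known PPAR targets were led by Hadhb, Plin2 and Cpt1a. Cpt1a (probe set 17355915), which encodes the enzyme that commits long-chain fatty acids to mitochondrial import, had a log2 level of 8.39 in control and 9.02 with bezafibrate, 1.54-fold higher. Plin2 (probe set 17426981), a lipid droplet coat protein and a common PPAR target, had levels of 6.36 and 7.19, 1.79-fold higher. Hadhb (probe set 17435748), the thiolase subunit of the mitochondrial trifunctional protein, had levels of 4.96 and 5.88, 1.90-fold higher. Its control level was close to the floor of 4.88. Acadl and Acadm, the long-chain and medium-chain acyl-CoA dehydrogenases, had ratios of −0.11 and 0.00, and the targets Angptl4 and Mgll had −0.14 and −0.23. Eci2 and Echs1, which also act in β-oxidation, had ratios of −0.33 and −0.24. Pdk4, a kinase that restrains pyruvate oxidation and a frequent marker of PPAR activity, was within background on both arrays. Cpt1b was read only by a probe set that also names Chkb and Gm44502, with a ratio of −0.12.

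As groups, these genes did not stand apart. Of 21 measured mitochondrial fatty acid oxidation genes, 13 were higher and 7 lower, with a median log2 ratio of 0.07 at percentile 88.5 of 10000 random lists of the same size and level. The mean of that list was 0.10, at percentile 98.2, so its place depends on whether the median or the mean is taken. That mean was pulled up by Hadhb (0.92) and Cpt1a (0.63), the 2 members at least 1.5-fold higher. With the trend in level and gene length subtracted the list's median was 0.02 (72.2). Of 30 classical PPAR targets, 13 were higher and 15 lower. Their median was −0.04 (percentile 27.1) and moved to either side with the processing. It was −0.09 (3.85) with probe sets that name several genes included, −0.07 (9.99) without the farthest member, −0.06 (15.4) with probe sets averaged, 0.01 for the 18 members above the floor and 0.01 (67.1) with that trend subtracted; the mean was 0.00. Peroxisomal oxidation genes had a median of −0.03 (percentile 33.6), with Ehhadh at 0.26 and Abcd3 at 0.25 against Phyh at −0.46 and Cat at −0.22; a second probe set of Phyh, within background, had 0.00. Among the receptors, Ppard had levels of 7.38 and 6.86 (ratio −0.53), whereas Ppara, Pparg and the coactivator gene Ppargc1a were within background on both arrays. The list of PPARs, coactivators and upstream regulators had a median of 0.07 (percentile 88.2), with Nrf1 at 0.30 and Ppargc1b at 0.29 against Rxrb at −0.22.

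Oxidative phosphorylation genes were lower together. Of 43 measured subunits of the respiratory chain and ATP synthase, 38 were lower with bezafibrate and 5 higher, with a median of −0.20 that was below all 10000 random lists matched on level (percentile 0.0). Atp5d, a subunit of ATP synthase, had levels of 9.21 and 8.59 (1.53-fold lower) on its brighter probe set and a ratio of −0.22 on the other, and the complex I gene Ndufs8 had 9.11 and 8.54 (ratio −0.56). Ndufs1 and Atp5a1 had ratios of 0.36 and 0.12. The list holds short genes, with a median length of 7510 bp, and short genes were lower in general; against random lists matched on level and gene length its percentile was 0.01. With the median of genes of like level and length subtracted, the list's median was −0.12. Other lists of central metabolism did not stand apart. The tricarboxylic acid cycle genes had a median of −0.05 (percentile 9.31) and glutamine and one-carbon genes −0.05 (19.3). Suclg1 had a ratio of −0.29, Sdhc −0.26, Pdk1 0.19 (−0.29 on a second probe set, within background) and Gpt2, within background on the bezafibrate array, −0.42. Glycolysis genes had a median of 0.03 (percentile 73.3), with Pfkfb3 at 0.33 and Pfkp at 0.32 against Slc16a3, a lactate exporter, at −0.35. Fatty acid synthesis genes had a median of 0.02 (69.3), with Acaca at 0.46 and Fads2 at 0.40 against Elovl1 at −0.24, and cholesterol synthesis genes −0.03 (22.7), with Stard4 at 0.32 and Mvd at −0.35.

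Inhibitory receptor and exhaustion genes were also lower as a group. Of 21 measured members, 14 were lower and 7 higher, with a median of −0.18 at percentile 0.23, and at 0.01 when gene length was matched too. Their mean was −0.12. The list was dim, and its median log2 level did not fall, at 5.27 in control and 5.36 with bezafibrate. Of its 16 members above the floor, 11 were lower and 5 higher, with a median ratio of −0.19. Among them, 0 were at least 1.5-fold lower and 0 at least 1.5-fold higher. Pdcd1, which encodes the checkpoint receptor PD-1, had levels of 4.89 and 4.52, the second within background, and the inhibitory receptor gene Cd200r1 had 5.16 and 4.83. Pdcd1 and Cd200r1 thus read close to the background limits, 4.71 in control and 4.68 with bezafibrate. Btla and Tox2 had ratios of 0.19 and 0.14. The genes of CD8 T cell identity were lower in 10 of 11 cases, with a median of −0.14 at percentile 1.62 and at 5.53 with length matched. Cd3d had a ratio of −0.30, Cd8b1 −0.23 and Cd8a −0.14, with Cd28 at 0.15. The identity list lay inside the central 95% also against random lists not matched on level (percentile 7.20) and after quantile normalization (2.63).

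Cytotoxic and effector molecules had a median of −0.09 at percentile 4.31, with 18 of 26 lower. Xcl1, a chemokine for cross-presenting dendritic cells, had levels of 7.65 and 7.05 (1.52-fold lower), and Gzmk 6.57 and 6.11. Gzmb was at 11.33 and 11.26 and Ifng within background on both arrays. The 20 members above the floor had a median of −0.13 at percentile 0.64; matched on gene length, the whole list was at 38.2, and its mean was −0.03 (30.9). Effector differentiation genes had a median of 0.04 (percentile 79.2). Klrc1, which encodes the inhibitory NKG2A receptor, was 1.58-fold higher (5.60 and 6.26), Zeb1 had a ratio of 0.31 and the transcription factor genes Batf and Irf4 −0.35 and −0.20. Naive and memory genes had a median of −0.05 (16.4), and 0.01 after quantile normalization. Cd44, an adhesion receptor of antigen-experienced cells, had a ratio of 0.43, Id3 −0.46 and S1pr1 −0.34.

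Cytokine and chemokine receptors had a median of 0.04 (percentile 83.8), with both chains of the interleukin-18 receptor highest. Il18rap had levels of 7.91 and 8.55 (1.56-fold higher) and Il18r1 8.38 and 8.80 (1.33-fold higher). Cxcr6 and Cxcr4 each had a ratio of −0.30. Cytokines with type 2 or type 17 genes had a median of −0.10 (7.19), with Ltb at −0.29 and Gata3 at −0.25 against Il13, within background in control, at 0.36 and Maf at 0.34. A second probe set had 0.11 for Gata3 and, within background, −0.24 for Maf, and the 14 members above the floor had a median of 0.09. Integrins and adhesion molecules had a median of 0.01 (56.7), with Itgae, which encodes CD103, at −0.41 and Icam1 at 0.22. T cell receptor signalling genes had a median of −0.02 (32.9), with Ptpn22 at 0.21 and Cd3d at −0.30.

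With the deposited values, survival and cell cycle lists lay inside the central 95% of random lists, the p53 list by a narrow margin. Anti-apoptotic genes had a median of 0.06 (percentile 83.6), with Xiap at 0.26 and Bcl2 at 0.13 (11.21 and 11.34), although a second, dimmer probe set of Bcl2 had −0.18. Pro-apoptotic genes had a median of −0.02 (40.0), with Diablo at 0.35, Bcl2l11 at 0.29, the death receptor gene Fas at −0.38 and Bbc3 at −0.36. Mitosis genes divided evenly, 12 higher and 12 lower, with a median of 0.00 (41.5) and a mean of 0.03. Mki67, the proliferation marker, had levels of 10.79 and 11.07, and Cenpe a ratio of 0.31 against −0.18 for Ccnb2 and Aurka. DNA replication genes had a median of 0.04 (75.5), with Pola1 at 0.34 and Mcm3 at 0.32 against Gins2 at −0.22. The p53 targets and cell cycle inhibitors were lower in 13 of 17 cases, with a median of −0.12 at percentile 2.84, and at 14.9 with length matched. The list passed the lower limit under 5 alternatives, at percentiles from 1.92 to 2.35. Phlda3 had a ratio of −0.32 and Perp −0.30, with Trp53inp1 at 0.15.

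Antioxidant genes and targets of NRF2, the transcription factor of the oxidative stress response, were lower in 20 of 21 cases. Their median was −0.18 at percentile 0.04, and at 0.29 with length matched. Hmox1, which encodes the haem-degrading enzyme induced by oxidative stress, had levels of 6.27 and 5.66 (1.53-fold lower), and Gpx1, a glutathione peroxidase, 9.51 and 9.14 (1.29-fold lower). Txnrd1 had a ratio of 0.08. Ribosomal protein genes had a median of −0.19 at percentile 0.01, with 16 of 20 lower, among them Rps19 at −0.43 (10.27 and 9.84), although another probe set of Rps19 had 0.29, and with Rpl11 at 0.36. Their median length was 3510 bp, and with length matched the percentile was 9.78. Rps18, at −0.68 on its brightest probe set, had 0.06 on another, and with the probe set of smallest ratio for every gene the list had a median of −0.07 (percentile 9.69). Autophagy and lysosome genes were lower in 17 of 21 cases, with a median of −0.12 at percentile 1.53, at 3.64 with length matched and at 5.42 with no matching on level. Lamp1, a lysosomal membrane glycoprotein, had a ratio of −0.32 and Atg5 0.19.

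The remaining lists did not stand apart. Interferon-stimulated genes had a median of −0.06 (percentile 13.8), with Isg20 and Oas2 at −0.43 and Irf1 and Ddx58 at 0.23 and 0.22, and their 20 members above the floor had −0.11 at percentile 1.79. Amino acid response genes had a median of −0.05 (15.4), hypoxia response genes 0.04 (79.9), endoplasmic reticulum chaperones 0.03 (66.6) with a mean of −0.02, and housekeeping genes −0.02 (31.4). Trib3 had a ratio of −0.20 and Nars 0.19, Kdm3a 0.30, Sdf2l1 −0.22 and Polr2a −0.16.

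Markers of other cell types were mostly below the floor, though some, such as Ighm and Cd209a, were bright. Which cells these signals come from was not tested. The natural killer cell list had a median of 0.15 (percentile 96.5), with only Fcer1g above the floor and lower with bezafibrate; without Fcer1g the median was 0.25 at percentile 99.3. B cell markers had a median of −0.09 (26.8), with Cd79b at −0.55 and Ighm at −0.33 (levels of 9.05 and 8.72) above the floor. Further probe sets of Ighm above background had −0.27 and −0.26, and those within background ran from −0.73 to 0.33. The 3 B cell markers above the floor had a median of −0.33, at percentile 1.0. Dendritic cell markers had a median of −0.15 (8.83), with Cd209a at −0.45, and at −0.12 on a second probe set within background. Medians of the other marker lists were −0.14 for neutrophils (10.5) and for γδ T cells (22.5), 0.04 for macrophages and monocytes (83.6), 0.07 for CD4 T cells (82.7), 0.01 for mast cells and basophils (64.7) and 0.08 for red cells (77.3). Ccr2 had a ratio of 0.30 and Zbtb7b 0.27.

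**Figure D2:**
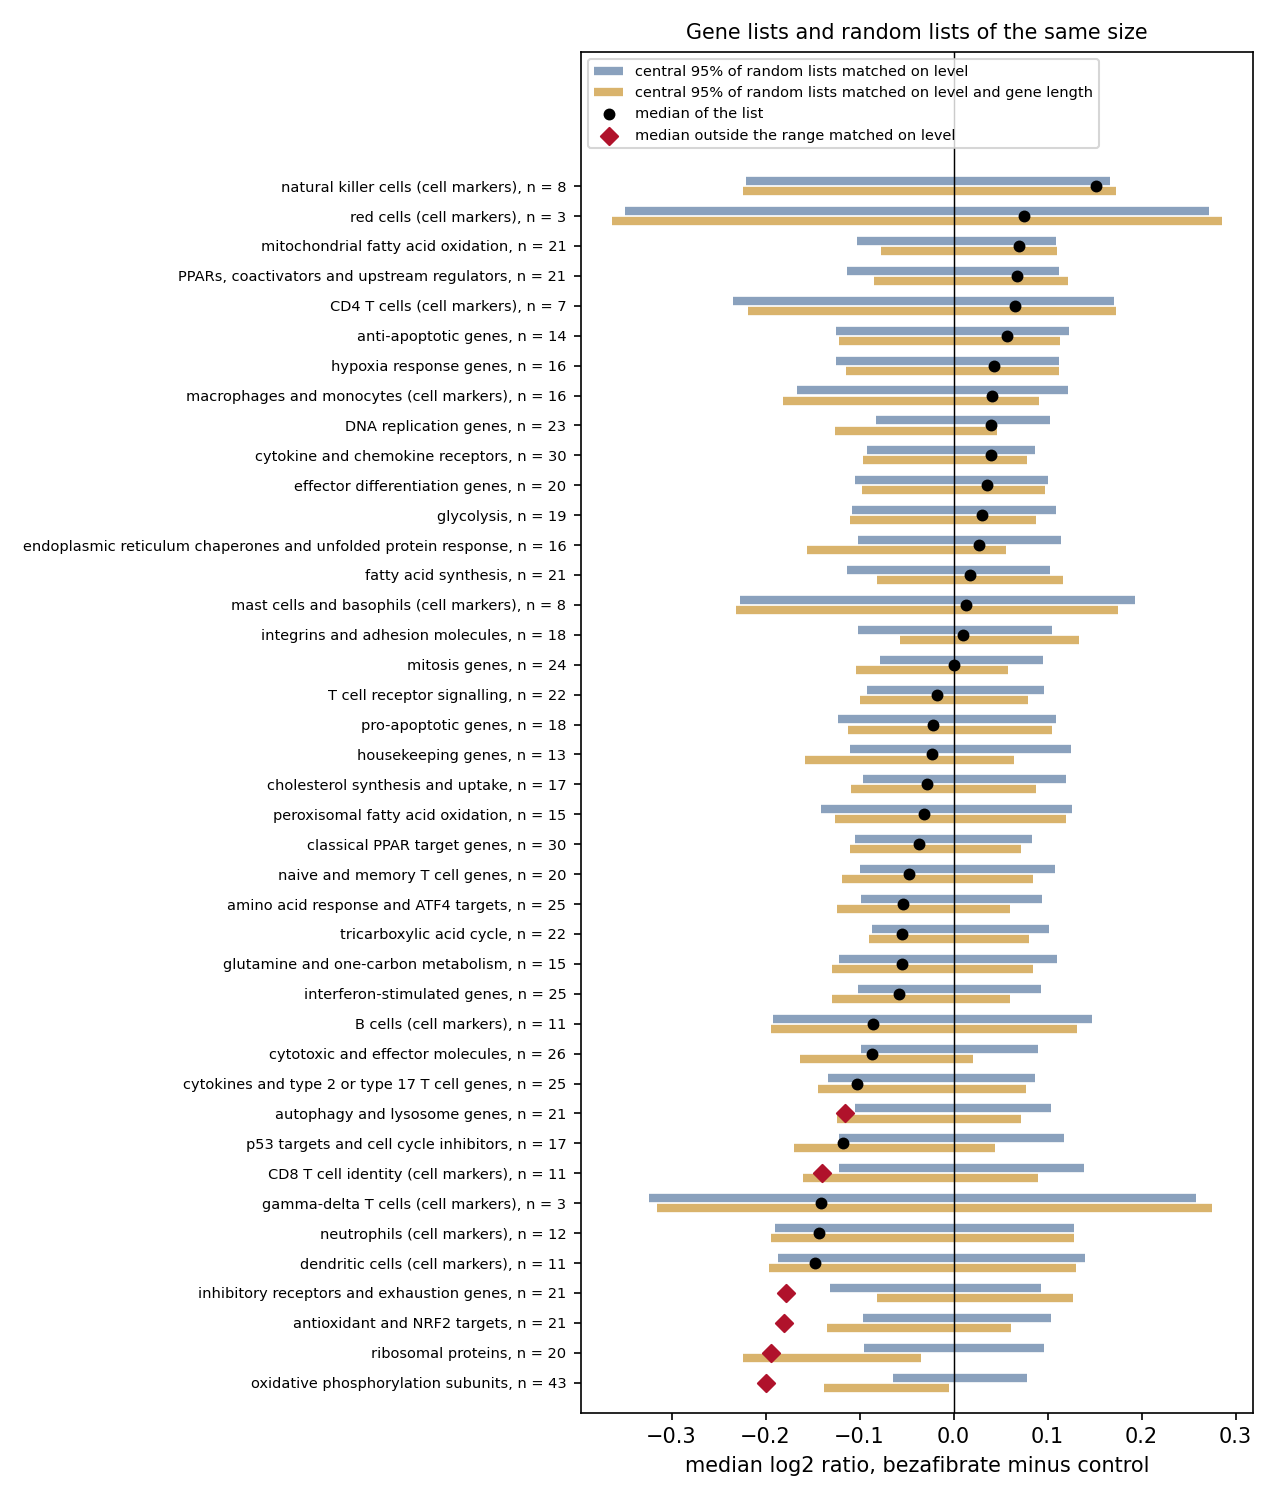
Median log2 ratio (bezafibrate minus control) of each of the 41 gene and cell marker lists, with n the measured genes; bars span the central 95% of 10000 random lists of the same size matched on level (blue) or on level and gene length (ochre). Red diamonds mark the 6 lists outside the blue range, all of them lower, of which oxidative phosphorylation, antioxidant and inhibitory receptor genes lie outside both ranges.

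Across the 41 lists, 6 lay outside the central 95% of random lists matched on level, where random draws of unrelated genes would place 2. Some lists share genes, and genes of like function can vary together between any 2 arrays. The 6 against 2 is therefore not a measured excess over chance. All 6 were lower with bezafibrate, and 3 of them also lay outside with gene length matched. That second matching was chosen after seeing the data.

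Short protein-coding genes were lower in the bezafibrate array and long ones higher. When the 10592 protein-coding genes above the floor were placed in 10 classes by length, the shortest class, from 297 to 4038 bp, had a median log2 ratio of −0.12 and 69.2% of its genes were lower. The longest class, from 103210 bp, had a median of 0.08 and 30.8% were lower. Spearman's rho between ratio and length, across genes, was 0.34 over these genes, 0.13 for genes with a mean log2 level under 6 and 0.49 for those of 9 or more. The ratios of Cpt1a and Plin2 after the median of genes of like level and length was subtracted were 0.53 and 0.77.

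**Figure D3:**
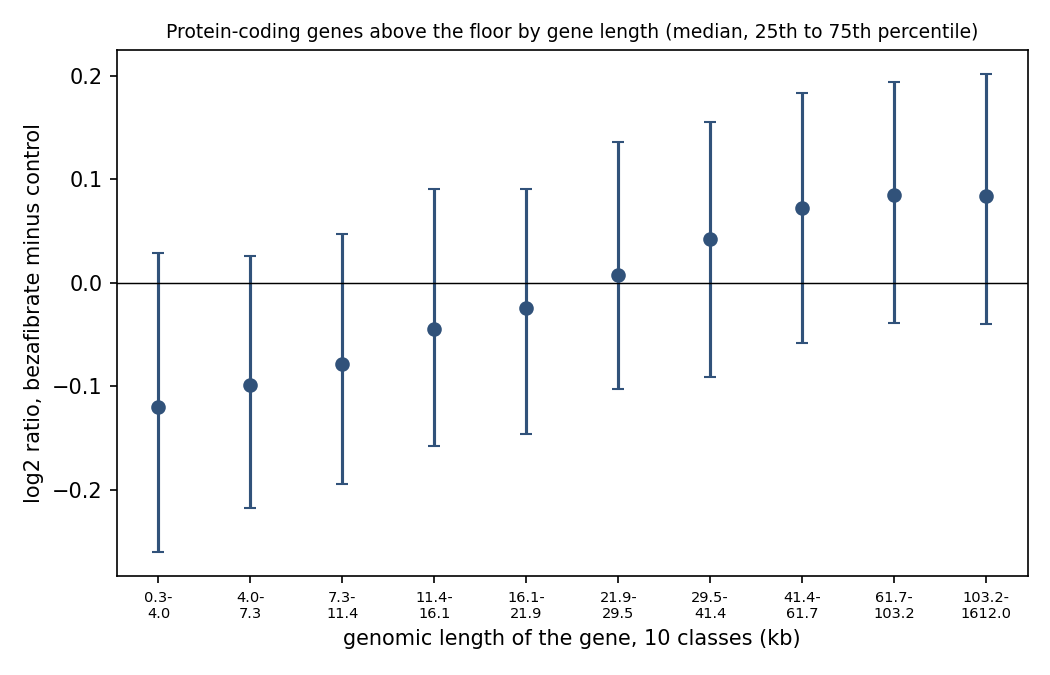
Log2 ratio (bezafibrate minus control) of protein-coding genes above the floor in 10 classes of genomic gene length in kb; points are medians and bars run from the 25th to the 75th percentile of genes. The median goes from −0.12 in the shortest class to 0.08 in the longest.

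Small nucleolar RNAs, which guide the chemical modification of ribosomal and spliceosomal RNA, were higher as a class. Of 68 above the floor, 62 were higher with bezafibrate and 5 lower, with a median log2 ratio of 0.48, and 25 were at least 1.5-fold higher while 0 were that much lower. Snord1b was 3.03-fold higher (5.18 and 6.78), Snora15 2.57-fold (6.26 and 7.62), Snord22 2.41-fold (8.08 and 9.35), and Snora34 2.22-fold (5.61 and 6.76). Under each scaling tried the class median stayed between 0.41 and 0.50. MicroRNA genes had a median of 0.10 over 138 genes, other short non-coding RNA genes −0.14 over 25 and long non-coding RNA genes 0.02 over 391. The class and its members were chosen after their values were seen.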

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

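Signals outside the gene comparison were looked at because they differed between the arrays as much as the genes counted in the report. Among 2495 probe sets above the floor that carry no gene symbol, 15 were at least 2-fold higher with bezafibrate and 3 at least 2-fold lower. Most rest on a level within background, which held for the control level of 12 of the 15 and the bezafibrate level of all 3. Of 907 probe sets above the floor that name several genes, 2 were at least 2-fold higher and 0 lower. Both name Snord1b and Snord1c, small nucleolar RNA genes, and had log2 ratios of 1.02 and 1.06, while the probe set that names Snord1b alone was 3.03-fold higher.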

How the results depend on the processing

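No paired analysis was possible because each group has 1 array, and for the same reason leaving out an array leaves no comparison. Matching on gene length and subtracting the length trend were chosen after seeing the data. Of 41 lists, 32 kept their side of the limit under each alternative run, among them oxidative phosphorylation, antioxidant and inhibitory receptor genes. The medians of 37 moved by over 1.5 times or changed sign under some alternative other than housekeeping centring. Of 171 named genes, 4 that differed at least 1.5-fold changed direction, and 9 lists with medians within 0.05 of 0 changed sign under quantile normalization, loess or the trend. Signal over background limits the dimmer genes, and the cause of the changes below was not tested except where the setting itself gives it.

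Genes at least 2-fold higher numbered 10, against 76 at 1.5-fold, 2 at 3-fold, 20 with no floor and 3 with the floor at the 75th percentile. Genes at least 2-fold lower numbered 0, against 60 at 1.5-fold, 20 with no floor and 1 with the length trend subtracted. At 1.5-fold, 55.9% of the genes that differed were higher, against 50.8% with no floor, 62.5% centred on housekeeping genes, 63.6% with the length trend subtracted and 69.6% with the floor at the 75th percentile. The fatty acid oxidation list passed the upper limit by its mean (0.10, percentile 98.2), which Hadhb and Cpt1a pulled up.

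Lists that passed the lower limit under an alternative were cytotoxic molecules with only genes above the floor (−0.13), without the farthest member (−0.10) and with the probe set of smallest ratio (−0.13); p53 targets with only genes above the floor (−0.12), quantile normalization (−0.12), loess (−0.12), the probe set of smallest ratio (−0.12) and shared probe sets included (−0.12), from percentile 2.84 to at most 2.35; interferon-stimulated genes above the floor (−0.11); and 3 B cell markers above the floor (−0.33). Natural killer cell markers passed the upper limit without the farthest member (0.25) and with shared probe sets included (0.20).

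Lists that returned inside the limits were ribosomal proteins with the probe set of smallest ratio (−0.070), the trend subtracted (−0.053) and length matched (−0.19, percentile 9.78); autophagy genes with no matching (−0.12), the trend subtracted (−0.064) and length matched (−0.12); and CD8 identity with no matching (−0.14), quantile normalization (−0.12), the trend subtracted (−0.10) and length matched (−0.14). With the probe set of smallest ratio, Dpep2 had −0.40, Rps18 0.060 and Tlcd1 −0.14; with shared probe sets included, Eif4a3l1 had 0.038.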

Other observations

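The gene families in the first paragraphs were chosen after their values were seen, as were the tests on small nucleolar RNAs, the test of Cpt1a and Plin2 against gene length and the count of arrays per group. Since the families were picked by their values, their percentiles only describe them and are no support for a difference. The limits of the other tests were set before their results were seen, but after the patterns that they address. Matching on gene length was itself chosen after seeing the data.

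Guanylate-binding protein genes, interferon-γ-inducible GTPases of cell-autonomous defence, were higher with bezafibrate in 8 of 8 members above the floor. The family's median log2 ratio was 0.20, at percentile 99.7 of random lists matched on level and 99.8 with gene length matched. Gbp11, annotated as a transcribed pseudogene, had levels of 6.35 and 6.82, Gbp4 8.66 and 9.12, and Gbp9 7.79 and 8.03. With shared probe sets included the family's median was 0.15, and how far its probe sets read each other was not tested. The interferon-stimulated gene list fixed beforehand had a median of −0.06. The interleukin-18 receptor genes Il18rap and Il18r1 had ratios of 0.64 and 0.42. Killer cell lectin-like receptor genes, which encode activating and inhibitory receptors of natural killer and memory CD8 T cells, were higher in 6 of 6 members above the floor. The control level of Klrc2, among the 6, was within background. Over all 22 genes the median was 0.12, at percentile 98.7 and, with length matched, at 97.0, but 16 of the 22 were below the floor and within background, so that median mostly describes background. Klrc1 had levels of 5.60 and 6.26 and Klrd1, its partner chain, 9.26 and 9.44. Klrc1 and Klrc2 are close relatives, and how far their probe sets read each other was not tested.

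Histone genes were lower in 20 of 22 members above the floor, with a median of −0.20 over 33 genes. That median was below all 10000 random lists matched on level and at percentile 0.02 with length matched. The length classes of these very short genes also held small nucleolar RNA and microRNA genes, many of them higher. The length-matched percentile therefore does not test short length among protein-coding genes. With the class median subtracted, H1f1 went from −0.91 to −1.05, while the shortest class of protein-coding genes had a median of −0.12. H2bc9 and H1f1 were lowest, at −0.95 and −0.91, and H4f16 and H2ac20 had −0.64 and −0.52. H2bc21 was within background with bezafibrate, 1.18-fold lower against its limit. H2ac1 and H4c9 had 0.29 and 0.22. The DNA replication list, whose genes are used in the same cell cycle phase as replication-dependent histone genes, had a median of 0.04. The histone family also holds variant histone genes such as H2az1, so that comparison is not like for like. Mitochondrial ribosomal protein genes had a median of −0.12 (percentile 0.0, and 2.68 with length matched), proteasome genes −0.08 (0.7 and 16.02) and kinesin genes 0.03 (85.3 and 61.6). The medians of these 7 families kept their signs under each setting tried, but that of mitochondrial ribosomal genes was −0.045 with the length trend subtracted, that of histone genes −0.12 with shared probe sets included, and that of kinesin genes 0.0054 with the trend subtracted and 0.013 with the probe set of smallest ratio.

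The lists that stood apart were lower with bezafibrate, and short genes were lower in general, so a difference between the arrays that goes with gene length, as RNA quality or amplification can give, is a candidate explanation. For ribosomal proteins the tables fit it, with the list at percentile 9.78 once length was matched. Autophagy genes at 3.64 and CD8 identity genes at 5.53 also came inside the limits under that matching. As the whole cause, a length difference is argued against by oxidative phosphorylation genes at percentile 0.01, antioxidant genes at 0.29 and inhibitory receptor genes at 0.01. The oxidative phosphorylation median nevertheless went from −0.20 to −0.12 with the trend subtracted. Genomic length stood in for transcript length and GC content, which were not tested. Bezafibrate and any other difference between the cultures or arrays cannot be told apart, since each group has 1 array.

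Small nucleolar RNA genes were higher as a class, with a median of 0.48. The 163 microRNA and other short non-coding RNA genes above the floor had a median of 0.077, below the limit set for better recovery of all short RNA. Of these, 138 are microRNA genes, with a median control level of 5.60 against 7.23 for the class. Which RNA their probe sets read was not tested, so they do not decide it. The 25 that are not microRNAs, at −0.14 with a median control level of 6.99, argue against better recovery for the RNAs they cover. Most small nucleolar RNAs are cut from introns of host genes. As the whole cause, more host RNA is argued against by the hosts' median of 0.063. It is also argued against by 46 of 56 small nucleolar RNAs (82.1%) having a higher ratio than their host. The hosts themselves leaned higher, with 26 of 43 above 0 and their median at percentile 95.8 of random lists matched on level. The trend with gene length runs the other way, with a median of −0.12 in the shortest class of protein-coding genes. A biological difference in the processing or stability of small nucleolar RNAs may remain as a hypothesis. More host transcription stays open too, as only the level of host RNA was measured and the hosts leaned higher. A recovery difference specific to small nucleolar RNAs and any other difference between the cultures also remain, and none of these was tested.

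Cpt1a and Plin2 were the 2 PPAR targets at least 1.5-fold higher. Random lists of like size, level and length held 2 or more such genes in 2.21% of draws, and lists matched on level alone in 4.55%; for the fatty acid oxidation list, with Cpt1a and Hadhb, the shares were 0.23% and 0.6%. The limit of 5% set for this count took no account of these being picked from 41 lists for these genes, so a random draw stays open. With the length trend subtracted, Cpt1a went from 0.63 to 0.53 and Plin2 from 0.84 to 0.77, so most of each ratio remained. The smaller ratio, that of Cpt1a, lay between the limits set for and against the trend as cause, so those limits decided nothing. Direct activation of PPARs by bezafibrate could raise both genes, a hypothesis that stays open with 1 array per group, yet Angptl4 had −0.14 and the whole target list a median of −0.04, which ranged from −0.09 with shared probe sets included to 0.01 with the length trend subtracted.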
